A study of Mus musculus with 12 samples.

How the data were processed

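Histone H3 acetylated at lysine 27 (H3K27ac), a chromatin mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation with sequencing (ChIP-seq) in microglia, the resident macrophages of the brain. Per the labels' protocols, mice at postnatal day 30 received interleukin-33 (IL-33) or vehicle in a cerebral ventricle on 1 side, were killed 4 h later, and cortical microglia were purified on a Percoll gradient and by flow cytometry. The labels list 12 samples, namely H3K27ac libraries of 4 male and 4 female mice and input libraries of the 4 male mice. Every replicate is a separate mouse. In the sex comparison, p-values over libraries rest on a spread between mice that includes any effect of IL-33. They cannot separate sex from library batch. The labels state the sex of each mouse and not which mouse received IL-33.

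Per the submitters' processing notes, Bowtie2 and HOMER were used with the mouse build mm10 (GRCm38), and their versions are not given in the sources used here. The authors deposited 2 tables. The first holds, per the file headers, a normalised signal for 104981 regions of 500 bp in each H3K27ac library, as HOMER tags scaled to 10000000 tags per library, with the nearest gene, the distance to its transcription start site (TSS) and the annotation of each region. Per the same headers, a region was found in a peak set of the IL-33 libraries (19758 regions), of the vehicle libraries (9304 regions) or of both (75919 regions). The inputs have no value in these tables and were not analysed here. The second is the authors' deposited table comparing IL-33 with vehicle over 55386 regions described in its name as anchored on ATAC-seq, an assay of open chromatin. Per the file headers it gives a log2 fold change, a mean level, a standard error and a test statistic (scores), a p-value, an adjusted p-value and a log2 group value for IL-33 and for vehicle. The tool behind the authors' deposited table is not given in the sources used here, nor which mice stand in each group. Apart from 16 regions with no TSS, its regions lie more than 3000 bp from a TSS, so promoters have no IL-33 comparison here. The difference between the group values of the authors' deposited table correlated with its log2 fold change at 0.981 across regions, which are not independent replicates, so a positive value means higher signal with IL-33.

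Each library's column was matched to its mouse through the header. Header text gives 2 dates, 1 for the male and 1 for the female libraries, with single index reads in the male and dual index reads in the female libraries. The scaling factor in each header returned whole reads for 100% of the values, within 0.01 of a read. Library totals were 10019606, 8730637, 9537631 and 5160915 tags in male mice 1, 2, 5 and 6, and 3408218, 4133042, 3587800 and 2155209 tags in female mice 3, 4, 7 and 8. Regions held 32.9 to 47.3% of these tags. No library of a group is a second deposit of another, since each pair differed by more than sampling noise (chi-square per degree of freedom 1.77 to 7.02, over regions with at least 10 reads in a pair). Of the regions, 9.83% overlap the next region and share reads with it.

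The design fixed before the data were examined allowed 2 routes for IL-33, and since the column headers name no treatment the comparison rests on the authors' deposited table alone, with calls at an adjusted p under 0.05. The authors' deposited table lists an adjusted p for 40352 regions and none for 15034 regions, whose mean level is at most 2.73. Standard errors in the authors' deposited table lie below the bound set by read counting in 18.4% of all its regions and in 0.0223% of those with an adjusted p, so only the latter were used. That bound is the lowest possible, for reads split evenly between the groups. It therefore does not clear regions with few reads in 1 group, such as the largest rises. The highest standard error in the authors' deposited table is 0.678, so those of such regions may be understated. Their log2 fold changes may be understated too. At Chst14 the authors' deposited table gives 4.16, with group values of 0.81 for vehicle and 5.72 for IL-33. At Nars, with more signal, it gives -2.63, with group values of 6.78 and 4.13, which lie about that far apart. A region belongs to the nearest gene given in the tables, and 99.8% of the 18207 gene names matched the reference gene table of GRCm38.p6, which was used for names and gene bounds.

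The 28 gene lists, also fixed before the data were examined, cover NF-kB targets and feedback, AP-1 and immediate early genes, cytokines and chemokines, pattern recognition receptors, IL-33 receptor signalling, phagocytosis and opsonin receptors, complement, lysosome, homeostatic microglia, disease-associated microglia, interferon response, antigen presentation, STAT3 and cytokine feedback, glycolysis and hypoxia, cholesterol and lipid efflux, oxidative stress and NRF2, extracellular matrix remodelling, cell cycle, histone acetylation machinery and housekeeping, and key study genes. Markers of border macrophages, monocytes and neutrophils, lymphoid cells, neurons, astrocytes, oligodendrocyte lineage, endothelial and mural cells and erythroid cells complete them. For each list, the genes with at least 1 risen (or fallen) region were compared with all other genes in a two-sided Fisher's exact test. The median of the gene medians of log2 fold change was set among 10000 random lists matched on signal (two-sided permutation p, smallest 0.0002). Both were adjusted by Benjamini-Hochberg over the lists, and Fisher's test over both directions too. Both treat genes as independent. Neighbouring genes may not be, since called regions 20 to 50 kb apart had the same sign in 84.1% of pairs. The p-values of lists with neighbouring genes may thus be too small. Genes that rose or fell were also counted with regions adjusted over the list alone.

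Male and female libraries were compared with limma 3.58.1 (trend and robust) in R 4.3.3 on log2(tags + 1), over the 53348 regions with a mean of at least 10 tags, with Benjamini-Hochberg adjustment and autosomes, X and Y counted apart. A difference is on that log2 scale and understates changes of low regions. A group without a read was given a floor of 3 reads over the group's summed depth, and intervals of single shares are Wilson intervals at 95%. Intervals and floors cover counting error only. Tested on simulated counts for the 53348 regions, limma recovered 1% of 100 regions changed 2-fold and 36% of 100 changed 4-fold, and 2.63% of its calls were false (1 call). The counts were simulated with 1 dispersion for all regions and no batch or treatment effect. They do not measure the false calls of the fit on the real libraries. The permutation test of lists, tested on the 7838 genes, gave p under 0.05 for 4% of 200 unshifted lists and for 100% of 50 lists shifted by 1 log2 unit. Those lists were random genes, so the rate does not cover lists with neighbouring genes. The shift exceeds all list medians except those of the NF-kB and cytokine lists. Fisher's test was not checked in this way. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

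Genes were named by a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls, with 1 region per gene, that of the smallest adjusted p, a level above the median and no Gm, Rik, Mir, Snor or LOC name. It adds the key study genes whatever their values, up to 4 members of each list with the smallest adjusted p, and the 5 genes with the most called regions in each direction. For sex it takes the 5 autosomal genes with the smallest adjusted p in each direction, and Xist, Kdm5d, Ddx3y, Eif2s3y and Uty. Alternatives for sex were a pseudocount of 8, no minimum level or a mean of at least 30 tags, TMM rescaling, quantile normalisation, array weights, a threshold of 0.10, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered whole reads, and leaving out each library. To test depth, male reads were also drawn down at random to the female depths, 20 times, and the limma fit repeated. For IL-33 they were an adjusted p under 0.01, a log2 change of at least 1, signal above the median, the best region per gene, random lists matched on the number of regions, regions that overlap no stronger region, and autosomes alone. Motif words were left out because no genome sequence was used here.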

Results

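H3K27ac was measured in 8 libraries of cortical microglia, 1 per mouse, from 4 male mice (mice 1, 2, 5 and 6) and 4 female mice (mice 3, 4, 7 and 8) at postnatal day 30. Each mouse had received IL-33, an alarmin cytokine of the IL-1 family, or vehicle 4 h earlier. Male libraries held 5160915 to 10019606 tags and female libraries 2155209 to 4133042. The median 500 bp region held 10, 9, 9 and 5 reads in male mice 1, 2, 5 and 6, and 3, 4, 4 and 2 reads in female mice 3, 4, 7 and 8. Regions without a read made up 11.8 to 17.1% of all regions in male and 28.8 to 35.7% in female libraries. Of the 104981 regions on build mm10, 22160 lie within 1000 bp of a TSS and 72994 more than 3000 bp away.

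The main comparison asked which distal regulatory regions gained or lost H3K27ac 4 h after IL-33. In the authors' deposited table, 4115 distal regions rose and 3226 fell with IL-33, together 18.2% of the 40352 regions with an adjusted p. The authors' deposited table gives a median log2 fold change of 1.51 for the risen and of -1.23 for the fallen regions. Changes of at least 2 log2 units were 1048 rises and 260 falls in the authors' deposited table. Among 7838 nearest genes with a tested region there, 1261 had only risen regions, 1376 only fallen regions and 261 had both. A nearest gene is an assignment by position, and no expression was measured here.

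The largest rise lay in an intron of Tnip1, which encodes a partner of the NF-kB inhibitor A20 (chromosome 11, 54936360 to 54936860, 26.3 kb from the TSS). The authors' deposited table gives it a log2 fold change of 4.86 (SE 0.59, adjusted p = 5.37e-14), with its vehicle value listed at 0 and its IL-33 value at 5.21. With no vehicle signal, that SE may be understated. Jade2, a subunit of a histone acetyltransferase complex, followed with 4.54 in an intron in the authors' deposited table. An intron region of Pik3cg, the catalytic subunit of PI3-kinase gamma (chromosome 12, 32193580 to 32194080), rose by 4.52 (SE 0.50, adjusted p = 5.6e-17) in the authors' deposited table, and 15 of the 25 tested regions of the gene rose. A region of Bcl2l1, which encodes the survival factor Bcl-xL, rose by 4.31 in the authors' deposited table. An intergenic region 13.1 kb from Dusp2, a MAP kinase phosphatase, rose by 4.07, and 1 beside the copper transporter gene Slc31a2 by 3.99 (adjusted p = 1.29e-18) in the authors' deposited table. The other large rises in the authors' deposited table were at Smndc1 (4.30), Zdhhc6 (4.30), Nfkb1 (4.21), Chst14 (4.16), Wsb1 (4.12) and Unc93a (4.08). By number of regions, the authors' deposited table lists 30 rises of 66 tested at Marcks, which encodes an actin-binding protein kinase C substrate, 28 of 62 at the ETS repressor gene Etv6 and 25 of 41 at 6330407A03Rik. Next in the authors' deposited table come the transcription factor gene Zeb2 with 21 rises of 66 tested, and Mir5129 on the same part of chromosome 2 with 19 of 38.

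Among the falls, an intron region of Kdm1b, a histone H3K4 demethylase gene (chromosome 13, 47056114 to 47056614, 12.9 kb from the TSS), fell by 3.03 log2 units (SE 0.41, adjusted p = 1.7e-11) in the authors' deposited table. An intron region of Nars, which encodes the asparaginyl-tRNA synthetase (chromosome 18, 64511229 to 64511729), fell by 2.63 (SE 0.26) with the smallest adjusted p among these 12 falls, 1.71e-21 in the authors' deposited table. Regions at Cbx7, a Polycomb subunit gene, and Kcnk2, a potassium channel gene, stood at -2.57 and -2.58 in the authors' deposited table. The authors' deposited table also lists Naaladl2 (-3.02), D7Ertd443e (-2.83), Pgpep1l (-2.70), Cdh26 (-2.67), Plekhg5 (-2.66), Engase (-2.57), Cln8 (-2.56) and Rtf2 (-2.56). Sall1, the transcription factor gene that marks microglial identity, had the most falls in the authors' deposited table, 19 of 56 tested regions and no rise, the best at -0.92 (adjusted p = 0.002). The TGF-beta receptor gene Tgfbr2 had 13 falls of 44 tested regions (best -1.31, adjusted p = 2.7e-09) in the authors' deposited table. Sipa1l2 had 16 falls of 52 tested regions and 1 rise in the authors' deposited table. Zfp36l2, which encodes an mRNA decay factor, had 14 falls of 33, and its neighbour on chromosome 17, 4933433H22Rik, 16 falls of 36 in the authors' deposited table.

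**Figure D1:**
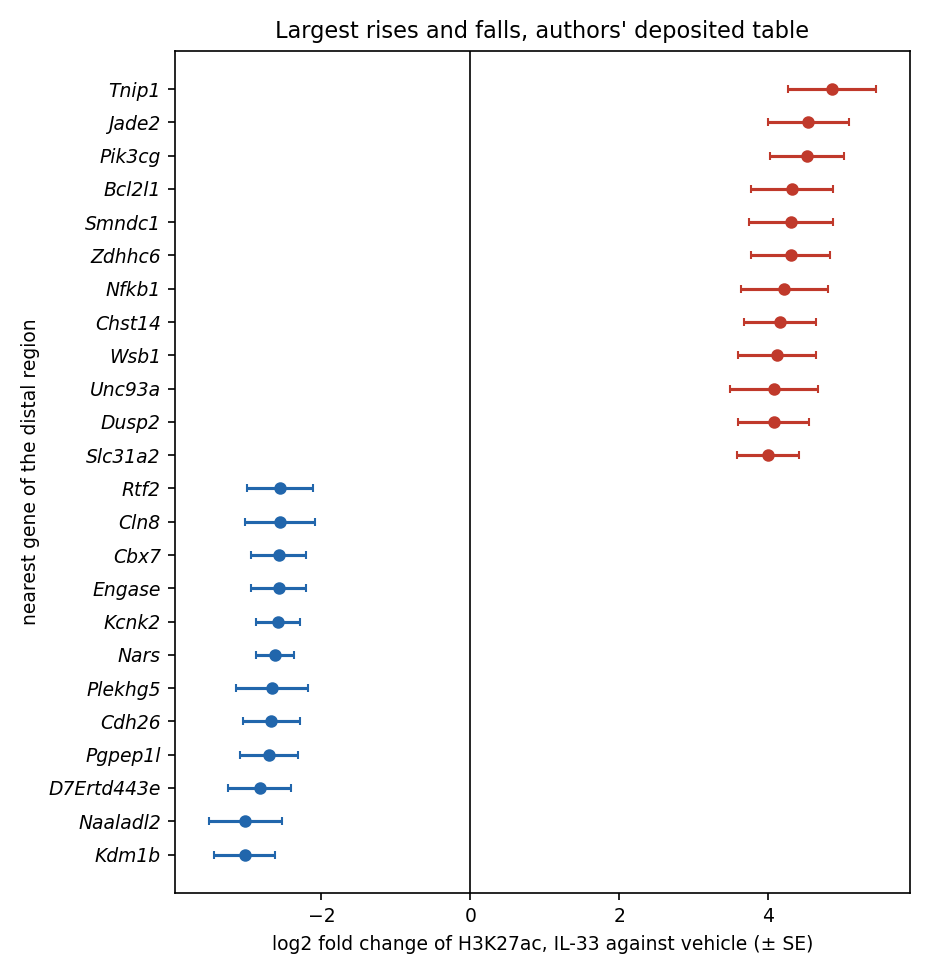
Log2 fold change of H3K27ac (x axis, IL-33 against vehicle, with the standard error as bars) for the 12 largest rises (red) and 12 largest falls (blue), 1 distal region per nearest gene (y axis), from the authors' deposited table. The rises span 3.99 at Slc31a2 to 4.86 at Tnip1, and the falls reach -3.03 at Kdm1b.

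Genes of NF-kB signalling, cytokines and the STAT3 pathway had risen regions more often than other genes. Of the 17 NF-kB target and feedback genes with a tested region, 12 had only rises, 1 had rises and falls and 4 had neither in the authors' deposited table. They include Zc3h12a, which encodes the endoribonuclease regnase-1 (2.54, 11 regions rose), Cd83 (1.42, 10 rose) and Nfkbia, the NF-kB inhibitor gene (2.80, 9 rose), in the authors' deposited table. In the authors' deposited table, 12 of 20 cytokine and chemokine genes had only rises, 1 had both, 1 only a fall and 6 neither, with Cxcl16 at 3.26, Ccl5 at 2.19 and Il10 at 3.80 (7 of 7 regions rose). The gene with only a fall was Il6, at -1.31 in the authors' deposited table, named here after its values were seen. Of 19 STAT3 and cytokine feedback genes, 12 had only rises, 2 only falls, 1 both and 4 neither, with Bcl6 at 3.14, Il21r at 1.76, Cebpd with 4 of 11 regions risen and Socs3, a feedback inhibitor of cytokine signalling, at 3.57 in the authors' deposited table. Rises were found at 76.5% of the NF-kB genes, 65.0% of the cytokine genes and 68.4% of the STAT3 genes, against 19.3% of other genes in the authors' deposited table (Fisher's exact test, adjusted p = 1.62e-05, 0.000117 and 6.25e-05). With regions adjusted over the list alone, 14, 15 and 13 of these genes rose, and 2, 2 and 3 fell. The list medians of log2 fold change in the authors' deposited table were 1.07 for NF-kB, 1.11 for cytokines (permutation, adjusted p = 0.0028 for both) and 0.36 for STAT3 (adjusted p = 0.0952). With the best region per gene they were 2.54, 1.80 and 1.23 in the authors' deposited table (permutation, adjusted p = 0.0028, 0.0028 and 0.0112).

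Receptors of pattern recognition and phagocytosis and AP-1 genes also held more risen genes than the rest. Of 26 pattern recognition receptor genes, 11 had only rises, 2 only falls, 2 both and 11 neither, among them Tlr2 (3.83), its partner Tlr1 (3.54), the co-receptor gene Cd14 (1.32) and the scavenger receptor gene Marco (3.19) in the authors' deposited table. Of 25 phagocytosis and opsonin receptor genes, 10 had only rises, 2 only falls, 6 both and 7 neither in the authors' deposited table. The complement receptor gene C3ar1 rose by 2.47, Cd47, the gene of a signal that restrains engulfment, by 2.16 and Itgax by 1.24, while the best region of the scavenger receptor gene Stab1 stood at -1.51 in the authors' deposited table. Of 23 AP-1 and immediate early genes, 11 had only rises, 2 both and 10 neither, with Batf (2.68, adjusted p = 2.97e-37), Batf3 (2.82), Dusp2 and Dusp1 (1.11) in the authors' deposited table. Fisher's exact test gave adjusted p = 0.00349 for the 13 receptor genes, 2.43e-05 for the 16 phagocytosis genes and 0.000803 for the 13 AP-1 genes with a rise in the authors' deposited table. Adjusted over the list alone, 15, 16 and 13 genes rose and 5, 8 and 2 fell. Against random lists matched on the number of tested regions, the adjusted p was 0.0625 for the receptors and 0.0928 for AP-1 (0.0632 and 0.0579 with a coarser matching), so both calls were lost. The receptor list's median, 0.23 (permutation, adjusted p = 0.264), was 0.93 with the best region per gene in the authors' deposited table (adjusted p = 0.014). The medians of phagocytosis and AP-1 genes were 0.16 and 0.20 in the authors' deposited table (permutation, adjusted p = 0.46 and 0.37; with the best region per gene 0.83 and 0.78, adjusted p = 0.0588 and 0.0896). With calls at an adjusted p under 0.01, Fisher's test gave adjusted p = 0.0589 for the receptors and 0.0769 for AP-1.

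Genes of the homeostatic microglial state held more falls than other genes. Of the 30 homeostatic genes in the authors' deposited table, 13 had only falls, 2 only rises, 8 both and 7 neither. Falls were found at 70.0% of them against 20.7% of other genes in the authors' deposited table (Fisher's exact test, adjusted p = 5.23e-07; adjusted p = 0.047 against random lists matched on the number of regions). Rises were found at 33.3% of them against 19.4% (Fisher's exact test, adjusted p = 0.297). These genes have many tested regions, 595 over the 30 genes. Random lists matched on the number of regions held 14 fallen and 16 risen genes in the median, against 21 and 10 here. Adjusted over the list alone, 21 homeostatic genes had a fall and 10 a rise. Rhob had 7 falls (best -1.40) and the purinergic receptor gene P2ry13 stood at -1.14, whereas 13 regions of the fractalkine receptor gene Cx3cr1 rose (best 1.17) and the best region of Selplg stood at 1.98 in the authors' deposited table. The list's median log2 fold change was -0.12 in the authors' deposited table (permutation, adjusted p = 0.928), and -0.86 with the best region per gene (adjusted p = 0.0459).

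Of the 14 key study genes with a tested region, 7 had only rises, 2 only falls, 1 both and 4 neither in the authors' deposited table. Besides Tlr2 and Nfkbia, regions rose at the chemokine gene Ccl2 (2.93, 5 regions), the lipid scavenger receptor gene Cd36 (2.49), the growth factor gene Csf1 (2.20), Il1b (1.86), Fos (1.01, 6 rises and 1 fall) and the scavenger receptor gene Msr1 (0.86, adjusted p = 0.0145) in the authors' deposited table. The purinergic receptor gene P2ry12 stood at -0.70 (adjusted p = 0.0334) in the authors' deposited table. The best regions of Il1rl1, which encodes the IL-33 receptor ST2, Il33 itself, Tlr4 and Tmem119 were at -0.68, 0.10, 0.78 and 0.55 with adjusted p of 0.433, 0.937, 0.424 and 0.0989 in the authors' deposited table, past no threshold. Fisher's exact test for the rises gave adjusted p = 0.0136 in the authors' deposited table, and adjusted over the list alone 8 genes rose and 3 fell. Against random lists matched on the number of regions the adjusted p was 0.464, so that call was lost. Msr1 and P2ry12 are past an adjusted p of 0.05 and not 0.01.

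**Figure D2:**
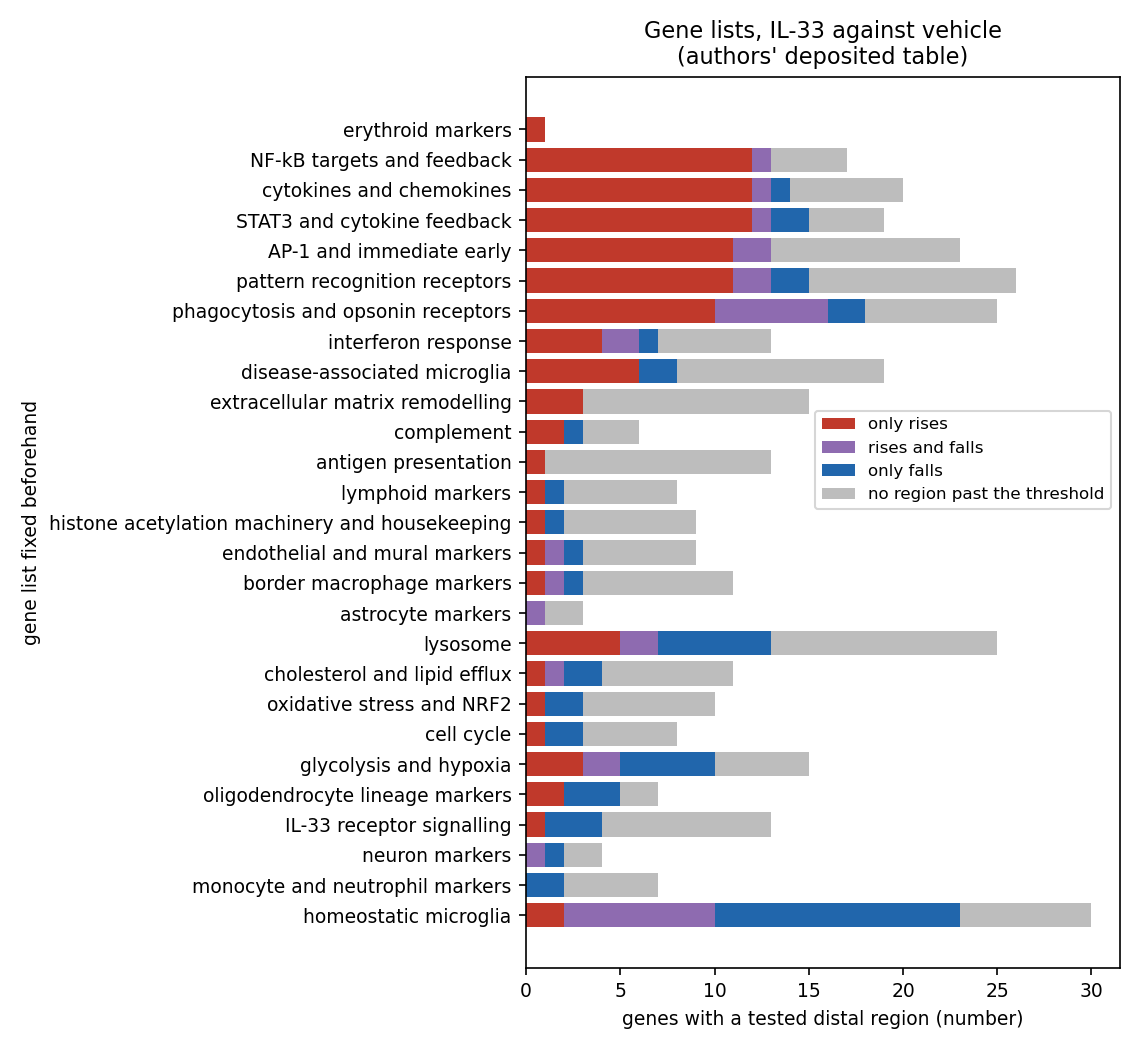
Number of genes (x axis) in each gene list fixed beforehand (y axis) whose tested distal regions only rose (red), only fell (blue), did both (purple) or passed no threshold (grey), IL-33 against vehicle, from the authors' deposited table. NF-kB genes held 12 with only rises among 17, and homeostatic microglia 13 with only falls among 30.

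At Nfkb1, which encodes the NF-kB subunit precursor p105, rises and falls lay in separate stretches of the gene (chromosome 3, 135584655 to 135691969). Of its 30 tested regions in the authors' deposited table, 4 rose by 2.46 to 4.21 log2 units between 135640105 and 135672874, 18.9 to 51.2 kb from the TSS. Farther into the gene, 11 regions between 135602042 and 135617173, 74.6 to 89.3 kb from the TSS, changed by -1.73 to -0.81 in the authors' deposited table. Regions of this gene are not independent replicates, and each call is that of the authors' deposited table.

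**Figure D3:**
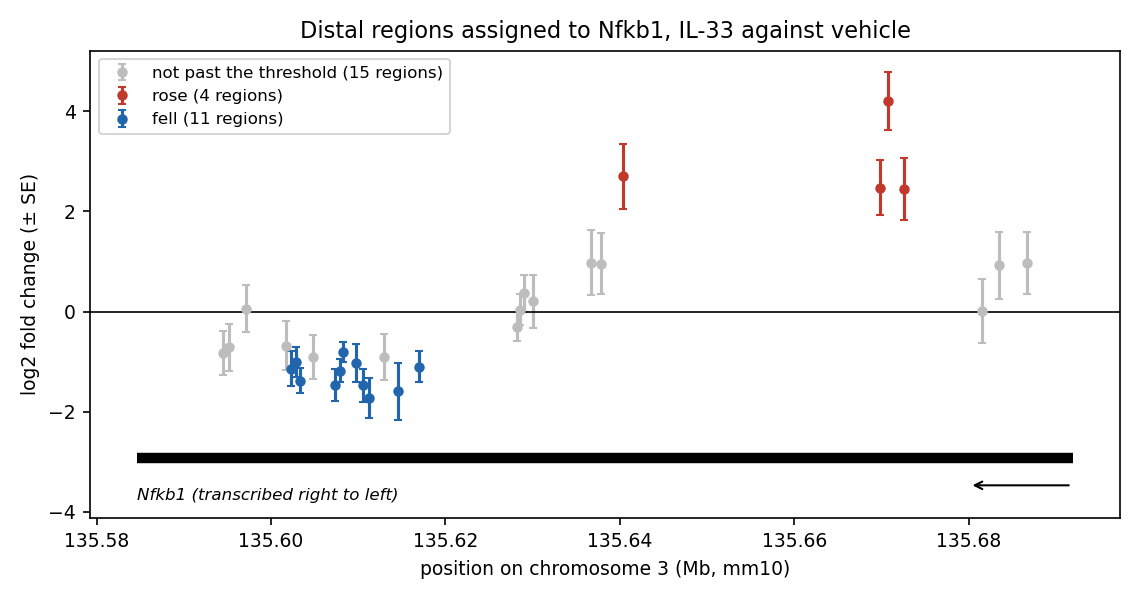
Log2 fold change (y axis, IL-33 against vehicle, bars are standard errors) of the 30 tested distal regions assigned to Nfkb1 by position on chromosome 3 (x axis, Mb, mm10), from the authors' deposited table, with the gene as a black bar whose TSS is at the right, as the deposited distances place it. The 4 risen regions (red) lie nearer to the TSS than the 11 fallen ones (blue).

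Risen regions were more often intergenic. In the authors' deposited table, 11.5% of intergenic regions rose against 9.37% of all others (Fisher's exact test, adjusted p = 1.98e-11). Of intron regions, 9.46% rose against 11.1% of others (same test, adjusted p = 1.04e-07). Of 750 exon regions 48 rose, or 6.4% against 10.3% of others (same test, adjusted p = 0.000727). Regions are not independent, since 98.6% of called pairs 1000 to 5000 bp apart had the same sign. The p-values of this paragraph may thus be too small. Regions more than 100000 bp from a TSS fell in 10.9% of cases in the authors' deposited table, against 7.69% of nearer regions (adjusted p = 5.5e-11), and rose in 8.53% against 10.4% (adjusted p = 0.000683). Regions 3000 to 10000 bp from a TSS fell in 6.84% of cases in the authors' deposited table, against 8.39% of others (adjusted p = 1.12e-06). By peak set, 22.3% of regions found only with IL-33 rose and 3.19% fell, and 4.25% of regions found only with vehicle rose and 14.1% fell in the authors' deposited table. The peak sets and the authors' deposited table come from the same libraries, so this is not independent evidence of direction.

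The second comparison asked which regions differ between male and female microglia, sex being stated for each mouse. Xist, the RNA that silences an X chromosome, had 66.8 ± 25.4 tags (SD, n = 4) in female and 0.263 ± 0.525 (n = 4, 1 read in all) in male libraries (limma, adjusted p = 0.00198). No female library had a read at the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d. In male libraries Ddx3y held 52.3 to 83.6 tags (mean 66.5), and Eif2s3y, Uty and Kdm5d held 74.1 ± 12.6, 40.1 ± 5.15 and 5.80 ± 4.76 tags (SD, n = 4). Over the group's floor of 3 reads, these were at least 29.4-fold, 32.8-fold, 17.8-fold and 2.57-fold lower in female. The adjusted p from limma was 0.00159 for Ddx3y, 0.00111 for Eif2s3y and 0.0129 for Uty, while Kdm5d was below the minimum level. On the Y, 5 of 22 tested regions were lower in female. Only 9 Y regions lie before 90 Mb, where female libraries held no read. Most of the 22 thus lie beyond it, where both sexes held reads. On the X, 23 of 1110 tested regions were higher in female and 5 lower (14 to 26 and 0 to 9 without 1 library). Uty lost its call without male mouse 1, 2, 5 or 6 (limma, adjusted p = 0.131, 0.166, 0.186 and 0.178, over all alternatives 1.11e-06 to 0.186) and Ddx3y without male mouse 2 (0.0507). With a mean of at least 30 tags, limma's adjusted p was 0.27 for Xist, 0.292 for Ddx3y and 0.246 for Eif2s3y, the highest of their alternatives, whose lowest were 1.61e-08, 1.02e-08 and 2.88e-09. Where these calls were lost, the differences stayed at -5.30 to -5.44 log2 units for Uty, -5.94 and -6.06 for Ddx3y, 5.75 for Xist and -6.21 for Eif2s3y (-5.35, -6.06, 5.75 and -6.21 with all libraries and the main filter).

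On the autosomes, lower signal in female libraries was found mainly at transcription start sites. The promoter region of Ugcg, the glucosylceramide synthase gene (chromosome 4, 59189204 to 59189704), had 226.0 ± 30.5 tags in male libraries (SD, n = 4) and no read in any female library, at least 100.1-fold lower (limma, adjusted p = 2.53e-05). At the promoter of Jak2, a cytokine receptor kinase gene (chromosome 19, 29251437 to 29251937), 760 reads in male libraries stood against 1 read in female ones, and at that of Galnt1 675 against 1. The promoter of the kinase gene Tlk1 had 290 ± 49.3 tags in male and 9.80 ± 3.74 in female libraries (SD, n = 4), and an intron region 343 bp from the TSS of Kpna3, an importin gene, 306 ± 19.2 and 11.6 ± 5.15. Higher in female libraries were Hist1h4a, a histone H4 gene (114 ± 17.8 against 37.4 ± 7.90 tags; SD, n = 4; limma, adjusted p = 0.00861), Adam6b (1.53 log2 units), Zbtb48 (1.67), Nek7 (1.19) and Gm16998 (0.99). Of 52126 tested autosomal regions, limma called 958 lower and 58 higher in female. The counts were 1573 and 7 with TMM rescaling, 1544 and 18 with quantile normalisation and 1451 and 18 with edgeR. DESeq2 called 1854 lower, and limma called 111 higher with array weights and 186 at a threshold of 0.10. The fit has no term for treatment, which the labels do not give per mouse, so the spread within each sex includes any effect of IL-33 among its mice. Within 1000 bp of a TSS, 885 of 15811 regions (5.60%) were lower in female, against 73 of 36315 (0.201%) elsewhere (Fisher's exact test, odds ratio 29.4, 95% interval 23.2 to 37.4). Regions are not independent, so intervals over them may be too narrow and p-values too small. Signal was also higher near a TSS, with a median male log2 value of 5.96 within 100 bp and 4.90 beyond 3000 bp. Fisher's test was not matched on signal. Regions higher in female lay less often within 1000 bp of a TSS (Fisher's exact test, odds ratio 0.478, interval 0.242 to 0.945, p = 0.0315), which was lost at 3000 bp (0.670, p = 0.181). Lower calls numbered 506, 540, 459 and 470 without male mouse 1, 2, 5 or 6, and higher calls 10, 5, 7 and 6, with 190, 34, 12 and 20 higher calls without female mouse 3, 4, 7 or 8. Sex coincides with header date, index reads and depth in every library, so the sexes and these batches cannot be told apart, and no date holds both sexes.

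Several calls of higher signal in female libraries were lost without single libraries or with another scaling, while the differences stayed at 1.10 to 1.23 log2 units for Nek7, 1.56 to 1.69 for Zbtb48 and 0.92 to 0.97 for Gm16998 where a library was left out. With TMM rescaling Nek7 stood at 0.86 and with quantile normalisation Gm16998 at 0.60. Nek7 lost its call with TMM rescaling and without male mouse 1, 2 or 6 or female mouse 7 (limma, adjusted p = 0.0544, 0.0624, 0.0743, 0.0554 and 0.051; all alternatives 0.00219 to 0.0743). Zbtb48 lost it without male mouse 1, 5 or 6 or female mouse 7 (0.0542, 0.0677, 0.0526 and 0.0549; all alternatives 0.00206 to 0.0677). Gm16998 lost it with quantile normalisation and without male mouse 5 or 6 (0.0624, 0.0803 and 0.0674; all alternatives 0.00466 to 0.0803).

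Regions lower in female were most frequent within 500 bp of the TSS. Their share was 5.75% within 100 bp, 7.29% from there to 500 bp, 3.13% to 1000 bp, 0.643% to 3000 bp and 0.128% beyond. Median differences, female minus male, were -0.07 within 100 bp and 0.30 beyond 3000 bp on the deposited scale, on which the median of all autosomal regions was 0.22. TMM rescaling moved that median to -0.10 and quantile normalisation to 0.08. Relative to it, TSS regions within 100 bp stood at -0.29, -0.29 and -0.34 and regions beyond 3000 bp at 0.08, 0.08 and 0.10 under the deposited scale, TMM and quantile normalisation. Where at least 50 female reads were expected from male tags, 203 of 10954 TSS regions held under 10% of them, against 12 of 13416 regions beyond 3000 bp. Reads within 1000 bp of a TSS made up 40.2 to 41.6% of region reads in male and 31.6 to 35.9% in female libraries, with Wilson 95% intervals of 31.5 to 31.7% for female mouse 7 and 40.1 to 40.2% for male mouse 6.

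**Figure D4:**
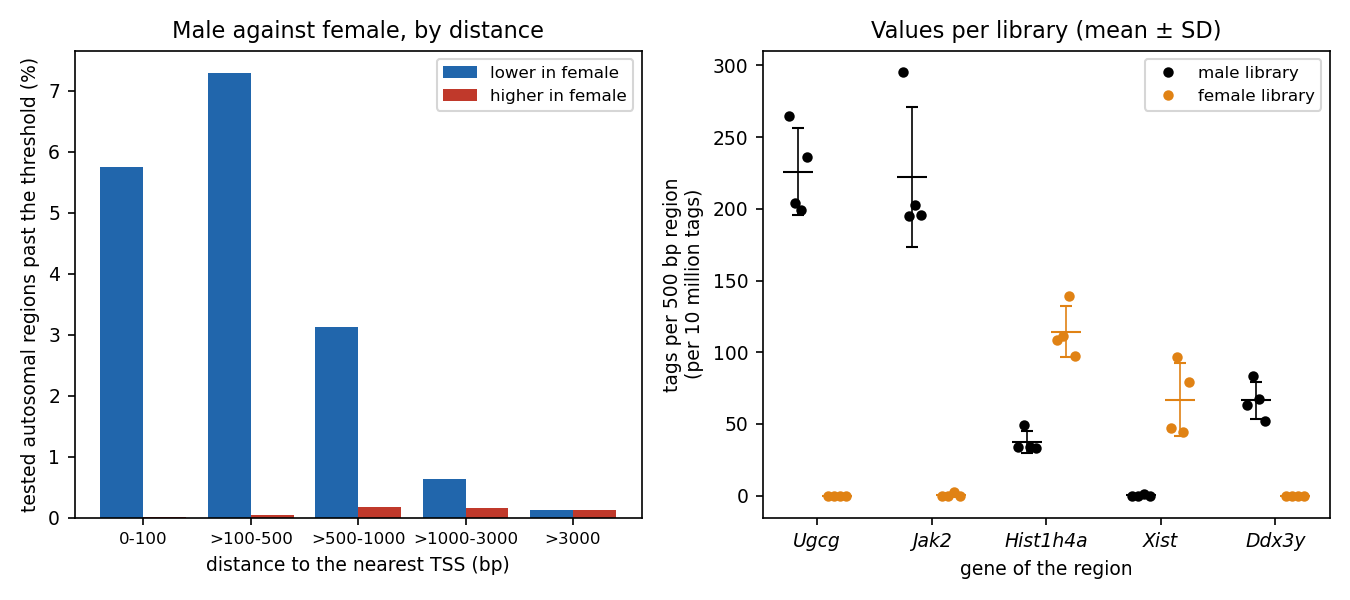
Left, percent of tested autosomal regions past the threshold (y axis) that were lower (blue) or higher (red) in female libraries, by distance to the nearest TSS (x axis, bp); right, tags per region scaled to 10000000 per library (y axis) at 5 genes (x axis) for each male (black) and female (orange) library with mean and SD. Lower calls peak at 7.29% between 100 and 500 bp, and Ugcg has 226.0 tags on average in male and no read in female libraries.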

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

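Of the tests in this part, those of depth, of batch and of other splits of the libraries were chosen only after the result was seen. Of 37 pairs of a group and a measure checked for a library far from the other 3 of its group, 7 had one. Chance gives about 1 in 20, which does not apply to 3 of them, a single read beside 3 libraries at 0. Among male libraries these were mouse 6 with 17.1% of regions without a read, mouse 1 with 363 tags at Tlk1 and 295 tags at Jak2, mouse 2 with 49.3 tags at Hist1h4a, and mouse 5 with 1.05 tags at Xist. Among female libraries they were mouse 7 with 2.79 tags at Jak2 and mouse 3 with 2.93 tags at Galnt1, each a single read, as is the Xist value. Some signals lie outside the comparisons or were not followed up. Female libraries held 825 reads in the 20 regions of the Y beyond 90 Mb, and none in the 9 regions before it, where male libraries held 1038. Regions beyond 90 Mb held 0.0128 to 0.0185% of region reads in female and 0.0103 to 0.0128% in male libraries. The unplaced contig JH584304 held 17854 reads over the 8 libraries. The 31870 regions within 3000 bp of a TSS have tags and no IL-33 comparison.

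The pattern most in need of a closer look is the lower signal at TSS regions in female libraries, 885 regions within 1000 bp of a TSS. Lower depth of the female libraries is argued against, since with male reads drawn down at random to the female depths limma called 842 such regions in the median of 20 draws (815 to 860; odds ratio for lying within 1000 bp of a TSS 27.6 to 32.9). Lower acetylation over the whole promoter is argued against too. Regions 1000 to 3000 bp from the TSS of 321 of the same genes differed by 0.20 (95% interval 0.12 to 0.29), against 0.21 at 2649 other genes. Within 1000 bp, the regions of these genes called lower stood at -2.26. That value is over regions picked for their calls and may overstate the difference, while regions 1000 to 3000 bp away were not picked by their values. A loss confined to the TSS may come from library preparation or from sex, and these cannot be told apart because 0 header dates are shared by male and female libraries; base composition was not tested, and sex remains an untested biological explanation. Of the 35 splits of the 8 libraries, 33 gave 0 autosomal calls and the split by sex gave 1016. The only other with calls, 6524, set mice 1 to 4 against mice 5 to 8. At the Tnip1 region mice 1 to 4 had 34.4 to 101.6 tags and mice 5 to 8 had no read. The vehicle value there is listed at 0 in the authors' deposited table. That split thus follows a structure of the samples that the labels do not name, and is no measure of chance. Counted over all 35 splits, 2 gave at least 1016 calls, the split by sex among them. Each of the 33 splits without a call mixes the sexes and also mixes mice 1 to 4 with mice 5 to 8. Differences along both divisions thus add to the spread within its sets, and its 0 calls are no measure of chance either. Neither chance nor a batch is therefore excluded for the 1016 calls.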

How the results depend on the processing

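The alternatives with random lists matched on the number of regions, regions that overlap no stronger region, autosomes alone and sex calls only beyond 3000 bp from a TSS were chosen after seeing the data. No paired analysis was possible because the labels do not tie mice to IL-33 or vehicle and the sexes share no mouse. For the same reason IL-33 fits per library, sums per gene, camera and fry, sex as a covariate and the interaction of sex and treatment were not run, nor were H3K27ac against input, promoter against distal calls for IL-33, and motif words. Over comparisons, 82 alternative values stayed within 1.5 times the main value or on the same side of the threshold, 48 moved and 1 lost its call; over single lists, 403 kept their side, 3 gained and 8 lost a call and 6 reversed; over named regions of the sex comparison, 217 kept and 20 lost it. The 6 list medians that changed sign in the authors' deposited table were past no threshold either way. With the best region per gene these were 0.0613 for neurons (against -0.56), 0.73 for astrocytes (-0.20), -0.42 for endothelial and mural cells (0.09) and 1.27 for erythroid cells (-0.49), and with regions that overlap no stronger region -0.0447 for oxidative stress and NRF2 (0.15) and 0.0355 for border macrophages (-0.05). Falls with IL-33 numbered 1830 at an adjusted p under 0.01, against 3226. Lists whose median stood apart numbered 5 with the best region per gene (pattern recognition receptors, STAT3 and homeostatic microglia added), against 2, and lists with more risen genes 4 with random lists matched on the number of regions, finely or coarsely, against 7. For autosomes, regions higher in male numbered 1573 with TMM, 1544 with quantile normalisation, 1451 with edgeR, 1854 with DESeq2 and 40 only beyond 3000 bp, against 958. Regions higher in female numbered 7 with TMM, 18 with quantile normalisation, 111 with array weights, 186 at a threshold of 0.10 and 18 with edgeR, against 58. On the X, regions higher in female numbered 11 with at least 30 tags and 39 at 0.10, against 23, and regions higher in male 10 with a pseudocount of 8, 3 with at least 30 tags, 10 with TMM, 10 with quantile normalisation, 9 with array weights, 8 at 0.10, 10 with edgeR and 13 with DESeq2, against 5. On the Y, 0 regions were higher in male by limma with at least 30 tags, against 5. Without 1 library, counts ran from 459 to 1373 (autosomes, higher in male), 5 to 190 (autosomes, higher in female), 14 to 26 (X, higher in female), 0 to 9 (X, higher in male) and 1 to 6 (Y, higher in male). The odds ratio of regions higher in female at promoters was 0.670 within 3000 bp. For these moves the cause was not tested. Depth limits the sex comparison, since female libraries hold 2 to 4 reads in the median region.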

Other observations

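Of the tests in this part, those of monocytes and of the number of regions per gene were chosen only after the result was seen. Of the lists of other functions, none had more risen or fallen genes than the rest, or a median apart from random lists, after adjustment. Of 19 disease-associated microglia genes, 6 had only rises, 2 only falls and 11 neither, with the lipoprotein lipase gene Lpl at 3.52 and Ch25h at 2.86 in the authors' deposited table. Of 13 interferon response genes, 4 had only rises, 1 only a fall, 2 both and 6 neither, with Ifitm3 at 0.99, Irf8 at 1.70 (4 rises, 5 falls), Irf1 at -1.59 and Ifit3 at -2.08 in the authors' deposited table. Of 15 glycolysis and hypoxia genes, 3 had only rises, 5 only falls, 2 both and 5 neither, with Pfkfb3 at 3.84, Pkm at 2.23 and Hk2 at 1.99 and, chosen after its values were seen, Bnip3 at -2.05 in the authors' deposited table (list median -0.31). Of 25 lysosome genes, 5 had only rises, 6 only falls, 2 both and 12 neither, with Laptm5 at 1.79 and Psap at -1.22 in the authors' deposited table. Of 13 IL-33 receptor signalling genes, 1 had only rises (Irak2, 1.26), 3 only falls (Map3k7 at -1.50, Chuk at -1.44 and Tab2 at -0.77) and 9 neither in the authors' deposited table. In the order only rises, only falls, both and neither, the authors' deposited table gives 2, 1, 0 and 3 for complement, 1, 0, 0 and 12 for antigen presentation, 1, 2, 1 and 7 for cholesterol and lipid efflux, 1, 2, 0 and 7 for oxidative stress and NRF2, 3, 0, 0 and 12 for extracellular matrix remodelling, 1, 2, 0 and 5 for cell cycle, and 1, 1, 0 and 7 for histone acetylation machinery and housekeeping. At the efflux transporter gene Abca1, 9 regions rose and 2 fell in the authors' deposited table.

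For markers of other cells, in the same order, the authors' deposited table gives 1, 1, 1 and 8 for border macrophages, 0, 2, 0 and 5 for monocytes and neutrophils, 1, 1, 0 and 6 for lymphoid cells, 0, 1, 1 and 2 for neurons, 0, 0, 1 and 2 for astrocytes, 2, 3, 0 and 2 for the oligodendrocyte lineage, 1, 1, 1 and 6 for endothelial and mural cells, and 1, 0, 0 and 0 for erythroid cells. Adjusted over the list alone, the authors' deposited table gives 1 fallen monocyte or neutrophil gene and 6 risen disease-associated microglia genes. Values of single markers in the authors' deposited table were 2.71 at Mbp, -1.75 at Opalin, 2.56 at Cldn5, -2.18 at Kdr, 3.25 at Rbfox1 (5 rises, 3 falls), -2.66 at Il7r and 2.06 at Dab2.

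Of 247 genes with at least 6 called regions in the authors' deposited table, 19 had at least 3 rises and 3 falls, chosen after their values were seen, such as Frmd4a (7 and 10), Lhfpl2 (9 and 8) and Tnfrsf1b (8 and 3), in each of which the rises stood on 1 side of the falls. That held for 9 of the 19, while the other 10 had 3 or 4 alternating runs. Reads shared by overlapping regions are argued against as the cause of equal signs, since 98.6% of called pairs 1000 to 5000 bp apart had the same sign (95% interval over 1 Mb blocks 98.0 to 99.2%, highest of 1000 shuffled sets 53.6%). Equal signs fell to 71.7% at 50000 to 100000 bp (65.8 to 76.9%) and 59.8% at 100000 to 500000 bp in the authors' deposited table. A hypothesis is that changes come in blocks along the chromosome that may span more than 50000 bp, which the fall with distance from 98.6 to 71.7% fits; no biological cause of such blocks was tested.

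For the lists that rose with IL-33, infiltrating monocytes or neutrophils could bring acetylation at inflammatory genes, although the cells were sorted by flow cytometry. The mean over the gene medians of the 7 monocyte and neutrophil markers tested was -0.25 (95% interval -0.50 to -0.03) in the authors' deposited table, below the 0.54 set as 50 percent of the NF-kB median; their best regions, a different measure, ran from -1.14 at Ccr2 to 0.13 at Ly6c2, the latter chosen after its values were seen. None of these 7 markers stands in another list. The list holds 20 markers, and those without a tested region were not compared. Promoters have no IL-33 comparison, and the interval is over genes and not over mice. Infiltration is therefore not excluded by these values. More tested regions per gene are argued against as the cause for the NF-kB, cytokine and STAT3 lists, since the largest adjusted p of the 3 lists was 0.0224 against random lists matched on the number of regions. A response of the microglia to IL-33 remains as a hypothesis, and with no treatment stated per mouse it was not tested per library.

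The labels give no treatment for single mice, so values per library stand here without a test. At the Tnip1 region, mice 1 to 8 had 83.8, 34.4, 91.0, 101.6, 0, 0, 0 and 0 tags. At the Nars region they had 29.9, 24.1, 52.8, 31.5, 176, 157, 259 and 334 tags. Both regions set mice 1 to 4 apart from mice 5 to 8. Only mice 5 to 8 had no read at the Tnip1 region, where the authors' deposited table lists the vehicle value at 0. The labels do not say whether mice 5 to 8 received vehicle.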
